A study of Homo sapiens with 6 samples.

How the data were processed

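Poly(A)-selected RNA from AC16 cells was sequenced after 48 h with 0.1% DMSO or with 100 nM doxorubicin. AC16 is a human cell line derived only in part from ventricular cardiomyocytes. Doxorubicin is an anthracycline that poisons type II topoisomerases. The libraries were unstranded and made with a TruSeq v2 kit, per the labels' protocols. Each treatment had 3 libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

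The deposited table holds raw counts per gene, 1 column per library, in the column layout of featureCounts per the file headers. The submitters' processing notes name STAR, SAMtools, Subread and featureCounts and the build GRCh38 (hg38), without versions or settings. Whether reads or read pairs were counted, and how reads in overlapping genes were handled, is not given in the sources used here. Because the libraries carry no strand, reads from a gene and an overlapping gene on the opposite strand cannot be told apart. The table lists 58299 Ensembl gene IDs with exon positions and summed exon length. Of these IDs, 57717 had a symbol in a gene name table, and 58179 were in GENCODE release 29 (GRCh38), which supplied the gene types and the names of the remainder. Start and end were identical to those of GENCODE release 29 for 57438 IDs. Coordinates are 1-based, as in the table, and span a gene's first to last exon. Counts cover exons only. Genes of the mitochondrial chromosome were not analysed here. No columns of other samples were present (0).

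Column totals ranged from 17252862 to 19571731 counts. Within a group, chi-square per degree of freedom over genes with 10 or more counts in a pair was 2.82 to 9.39, so every pair differed by more than sampling noise and each library was counted as 1 replicate. At this depth a gene at 0 in all DMSO libraries could be present at up to 0.0543 CPM (3 counts over the group), where CPM is a count scaled to the library total. Counting intervals are exact 95% intervals and cover counting error only.

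Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults (minimum count 10, minimum total 15), TMM scaling, robust dispersion, and the quasi-likelihood F test of doxorubicin minus DMSO without covariates, two-sided, with Benjamini-Hochberg adjustment over 15358 tested genes. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is approximate, the fold change divided by the square root of its F. Group values are TMM-scaled CPM as mean ± SD with n = 3. The procedure was also run on counts simulated from the means and library sizes of these libraries (15241 genes tested). It recovered 68.8% of genes changed 1.5-fold, 90.0% of those changed 2-fold and 98.0% of those changed 4-fold. It called 18 of 15043 unchanged genes. Only 48 to 50 genes were changed at each fold, balanced up and down, while 64.7% of the real tested genes were called. The simulation therefore cannot show how scaling or false calls behave when most genes change.

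There were 23 gene lists, written from textbook knowledge before the data were examined, and none was chosen on these samples. One list, the mitochondrially encoded genes, had no measured member. The other 22 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the 22 lists. Camera compares a list with the other genes. Camera was repeated with the correlation estimated per list from 4 residual degrees of freedom, and fry tested whether a list's genes moved, on balance, one way. List members were counted by their edgeR calls over all genes, and again adjusted over the list alone. The total given for a list counts only its measured members, those that passed the expression filter, unless stated otherwise.

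The rule for named genes was also set before the data were examined. It names a fixed set of genes (NFE2L2, KEAP1, NQO1, HMOX1, TXNRD1, CDKN1A, MDM2, TOP2A and TOP2B). It adds the 6 highest and 6 lowest log2 fold changes among called protein-coding genes with a mean log2 CPM of at least 2 and groups that do not overlap. From each list it takes the 2 called members with the largest absolute change and a mean log2 CPM of at least 1. Where 5 or fewer members of a list moved in one direction, they are named as well. Those members, and the genes of the closing section, were chosen after their values were seen. Some genes that the rule or a list count would name are not reported here.

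The alternatives tried, set before the data were examined, were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, the 50 most abundant genes left out, glmTreat against a 2-fold change, and other settings for the lists and for gene length. Scaling by library totals only was added after the data were seen.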

Results

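The transcriptome of AC16 cells was compared between 3 samples treated with 100 nM doxorubicin for 48 h and 3 treated with the vehicle, 0.1% DMSO. The series title places this comparison in a study of doxorubicin toxicity and of NRF2, the transcription factor that controls antioxidant and detoxification genes. Total counts were 17929419, 19571731 and 18573110 in DMSO replicates 1 to 3 and 17252862, 18665979 and 17844432 in doxorubicin replicates 1 to 3. Libraries of the same group correlated at r = 0.991 to 0.994 across genes on the log2 CPM scale, and libraries of different groups at 0.917 to 0.933. The first principal component held 88.3% of the variance and separated the treatments. Doxorubicin replicate 1 lay farther from the DMSO libraries on it (72.7) than replicates 2 and 3 (62.8 and 61.4).

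Doxorubicin changed most of the genes that passed the expression filter. Of 15358 genes tested, 5017 were higher and 4917 lower after doxorubicin in edgeR's quasi-likelihood test at an adjusted p under 0.05, together 64.7% of the genes. TMM scaling makes these changes relative, with a median log2 fold change of -0.0013, so a shift of all genes alike would not be seen. With library totals only, 5320 were higher and 4571 lower. With no filter, 6100 genes were higher and 5190 lower of 34828, and with DESeq2, 5035 were higher and 4494 lower of 22679. Large changes were mostly increases: 2185 genes rose and 961 fell at least 2-fold, 954 rose and 101 fell at least 4-fold, and 296 rose at least 16-fold against 1 that fell as much. Among 1245 lncRNA genes, 272 rose and 84 fell at least 2-fold. The 3 values of one group lay wholly above those of the other in 69.1% of tested genes, where chance gives 10%. When tested directly against a 2-fold change with glmTreat, 430 genes fell; with no filter on low counts, 3531 genes rose at least 2-fold.

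**Figure D1:**
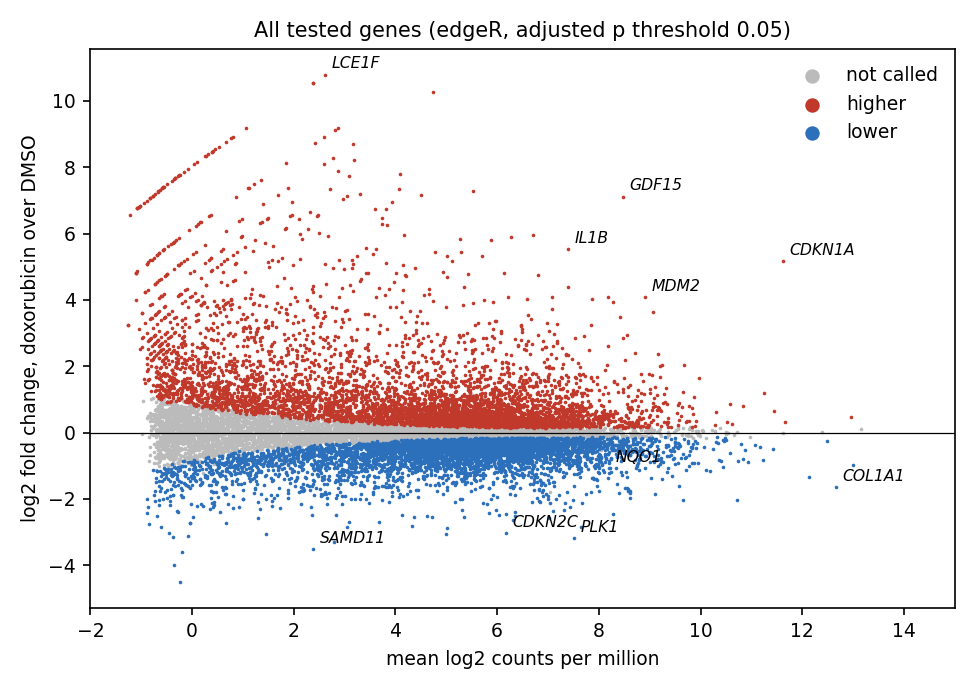
Log2 fold change (doxorubicin over DMSO, vertical axis) of the 15358 tested genes against their mean log2 CPM (horizontal axis); red points are the 5017 genes called higher, blue the 4917 called lower and grey those not called. The points reach farther above 0 than below it, and the diagonal strings of points are genes with few or no DMSO counts, whose fold change depends on the prior count.

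Among called protein-coding genes with a mean log2 CPM of at least 2 and groups that did not overlap, the 6 highest fold changes belonged to genes that were silent or nearly silent in DMSO. LCE1F (chr1:152776372-152776728, GRCh38), which encodes a late cornified envelope protein of the skin, had 0 counts in DMSO and 12.1 ± 4.22 CPM (SD, n = 3) in doxorubicin, at least 223-fold higher against a floor of 3 counts over the DMSO group. On the same terms POU3F1 (chr1:38044611-38046794), a POU-domain transcription factor, was at least 188-fold higher, and DSC3 (chr18:30990008-31042815), a desmosomal cadherin, also at least 188-fold higher. LCE1C (chr1:152804835-152806628) had 1 count in all DMSO libraries and 786 in doxorubicin, a ratio of 797 with a 95% counting interval of 143 to 31533. The lipid-sensing receptor gene TREM2 (chr6:41158506-41163186) had 1 and 750 counts, a ratio of 761 (136 to 30090). The neurofilament gene NEFL (chr8:24950955-24957110) had 1 and 573 counts, a ratio of 581 (104 to 22998). All 6 were called by edgeR, with adjusted p of 9.8e-06 or lower. LCE1 genes are near-identical copies of each other, so their counts are uncertain between copies.

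Under the same limits, the 6 genes with the lowest fold changes included regulators of the cell cycle. PLK1 (chr16:23677656-23690367), a mitotic kinase, fell 9.13-fold, from 330.5 ± 9.17 to 36.1 ± 8.76 CPM (adjusted p = 2.2e-06, edgeR). CDKN2C (chr1:50960745-50974633), an inhibitor of CDK4 and CDK6, fell 8.19-fold, from 128 ± 1.53 to 15.7 ± 0.711 CPM (adjusted p = 1.1e-14). SAMD11 fell 11.5-fold, from 9.39 ± 2.36 to 0.811 ± 0.268 CPM, and the ephrin gene EFNB3 fell 9.94-fold, from 12.3 ± 2.21 to 1.22 ± 0.507 CPM. The transcription factor gene ATOH8 fell 8.37-fold and SAPCD2 fell 7.31-fold. Exons of other genes cover 9.07% of the exon bases of SAMD11. The largest overlap is with opposite-strand NOC2L, with 28656 counts against 563. For SAPCD2 the share in exons of other genes is 22.9%, and the largest overlap is with an opposite-strand gene with 0 counts.

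The gene lists were compared next. By camera, 6 of the 22 lists were higher and 4 lower than the other genes after doxorubicin at an adjusted p under 0.05. With the inter-gene correlation estimated, 0 lists passed, and that p is given beside each call. Counts of called members adjusted over the list alone were the same as those over all genes in 18 lists, and the 4 exceptions are given with their lists.

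All 30 p53 target genes rose, 29 of them at least 2-fold, with a median log2 fold change of 2.96. CDKN1A (chr6:36676460-36687339), which encodes the cyclin-dependent kinase inhibitor p21, rose 35.9-fold from 170.1 ± 10.99 to 6099.8 ± 324 CPM (log2 fold change 5.16 ± 0.08 SE, adjusted p = 2.5e-16, edgeR). MDM2 (chr12:68808176-68850686), a ubiquitin ligase, rose 16.8-fold from 54.1 ± 4.21 to 911 ± 28.0 CPM. The stress cytokine gene GDF15 (chr19:18374731-18389176) rose 139-fold from 5.06 ± 0.755 to 703 ± 83.9 CPM, and the antiproliferative gene BTG2 rose 62.3-fold from 3.28 ± 0.0487 to 205 ± 31.8 CPM. The list was higher by camera (adjusted p = 1.5e-16; adjusted p = 0.33 with an estimated correlation).

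NRF2 target genes moved in both directions: of 30 members, 10 rose, 15 fell and 5 did not pass. Tested genes at large also moved both ways, with 5017 of 15358 higher and 4917 lower. The list's rising share was near theirs, and its falling share was larger. NQO1 (chr16:69706996-69726951), a quinone reductase, fell 2.11-fold from 400.4 ± 46.6 to 189 ± 15.97 CPM (log2 fold change -1.08 ± 0.09 SE, adjusted p = 4.4e-08, edgeR). TXNRD1 (chr12:104215779-104350305), thioredoxin reductase, fell from 760.1 ± 35.5 to 380.1 ± 19.2 CPM. PIR fell 4.47-fold from 12.5 ± 1.89 to 2.78 ± 0.33 CPM. In the other direction, HMOX1 (chr22:35380361-35394214), heme oxygenase, rose 3.03-fold from 21.7 ± 0.827 to 65.7 ± 6.44 CPM (adjusted p = 1.1e-10), and the aldo-keto reductase gene AKR1B10 rose 88.1-fold from 0.288 ± 0.0713 to 26.1 ± 1.28 CPM. AKR1B10 has close paralogs that can share reads. NFE2L2 (chr2:177227595-177392697), which encodes NRF2, fell 1.44-fold from 96.7 ± 6.65 to 66.9 ± 4.77 CPM, and KEAP1 (chr19:10486120-10503741), which encodes its repressor, fell 1.54-fold from 118 ± 4.19 to 76.6 ± 2.14 CPM. Of the exon bases of NFE2L2, 20.9% lie in exons of other genes, with the largest overlap in a same-strand gene with 155 counts. The list's median log2 fold change was -0.20, its mean was 0.14, and camera did not call it (lower, adjusted p = 0.41).

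**Figure D2:**
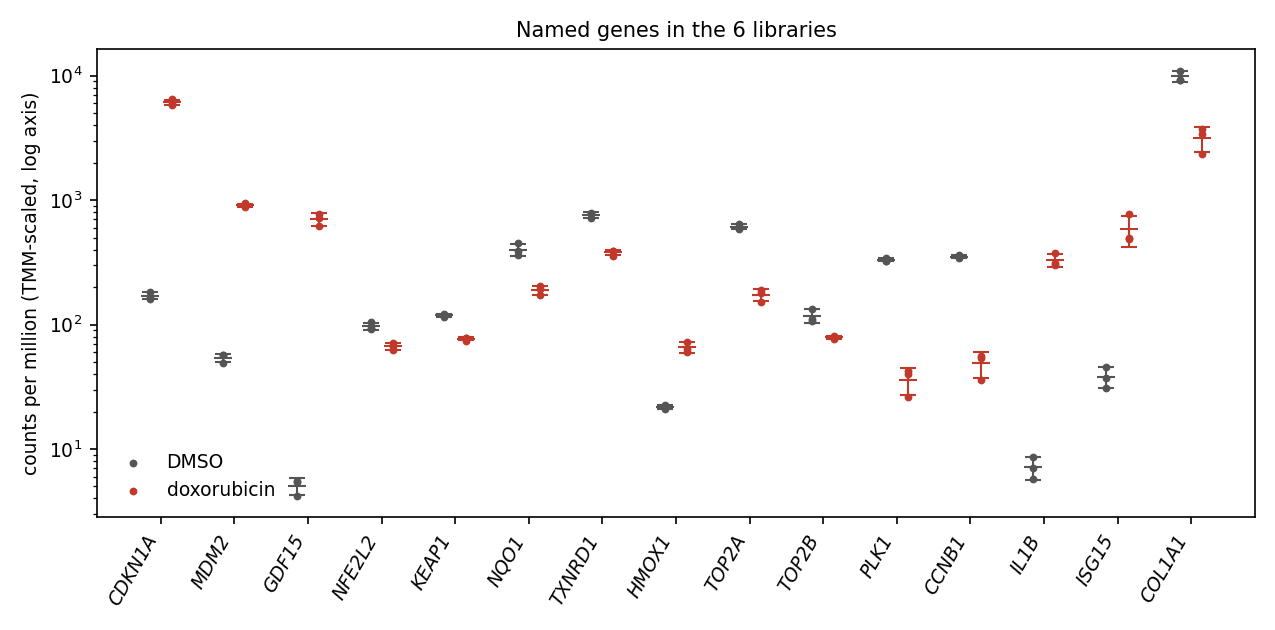
TMM-scaled CPM on a log axis for 15 genes in the 3 DMSO (grey) and 3 doxorubicin (red) libraries; points are libraries, and bars are mean ± SD. The 3 values of one group lie wholly above those of the other for each gene plotted, as for CDKN1A (170.1 against 6099.8 CPM).

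Genes of mitosis fell almost as a block: 29 of 30 fell, 26 at least 2-fold, with a median log2 fold change of -1.83. CCNB1, cyclin B1, fell 7.22-fold from 352 ± 10.6 to 48.7 ± 11.4 CPM, beside PLK1 above. The exception was PTTG1, which encodes securin and rose from 116 ± 3.81 to 135 ± 9.36 CPM (log2 fold change 0.22, adjusted p = 0.008). The list was lower by camera (adjusted p = 1.8e-12; adjusted p = 0.36 with an estimated correlation). Doxorubicin replicate 1 was lower than the mean of the other two by 0.33 on the log2 scale over this list; without it, 29 members fell.

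Of 32 DNA replication genes, 21 fell, 3 of them at least 2-fold, with a median log2 fold change of -0.29. MCM6, a helicase subunit, fell 2.69-fold from 167 ± 18.1 to 62.0 ± 2.32 CPM, and UHRF1, a DNA methylation maintenance factor, fell 2.61-fold from 336 ± 4.52 to 129 ± 5.54 CPM. PCNA, GINS4, TYMS, TK1 and GINS1 rose (5 members, or 6 adjusted over the list alone). The list was lower by camera (adjusted p = 0.014; adjusted p = 0.63 with an estimated correlation). Homologous recombination and Fanconi genes also fell, 15 of 25, with a median of -0.43; RAD51C was the 1 member that rose. FANCD2 fell 1.94-fold from 55.6 ± 3.26 to 28.6 ± 3.21 CPM and RAD54B fell 1.91-fold from 5.13 ± 1.28 to 2.68 ± 0.598 CPM. Exons of other genes cover 59.1% of the exon bases of RAD54B, with the largest overlap in FSBP, with 1 count. That list was lower by camera (adjusted p = 0.0013; adjusted p = 0.33 with an estimated correlation). Of 19 measured replication-dependent histone genes, 7 rose, all at least 2-fold, and 2 (H2BC17 and H2AC20) fell. H2BC8 rose 3.92-fold from 0.801 ± 0.153 to 3.14 ± 0.712 CPM and H2AC11 rose 3.44-fold from 3.40 ± 0.336 to 11.7 ± 0.199 CPM. Most replication-dependent histone transcripts lack a poly(A) tail, and the copies are alike in sequence. Camera did not call the list (adjusted p = 0.28). A filter of 1 CPM in 3 libraries removed H2BC17 and H2AC20 from the test, so 0 members fell under it.

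Secreted factors of the senescence programme rose. Of 25 measured senescence-associated secretory genes, 21 rose, 16 at least 2-fold, and 0 fell, with a median log2 fold change of 1.31, also with the 1 member at 0 counts in DMSO set at its bound. IL1B, interleukin 1 beta, rose 46.1-fold from 7.11 ± 1.48 to 329 ± 40.7 CPM (log2 fold change 5.53 ± 0.14 SE, adjusted p = 7.1e-11, edgeR), and the EGF-receptor ligand gene AREG rose 30.7-fold from 0.484 ± 0.229 to 15.2 ± 5.43 CPM. The list was higher by camera (adjusted p = 5.5e-06; adjusted p = 0.33 with an estimated correlation). Of 27 measured interferon-stimulated genes, from 35 in the list, 20 rose and 0 fell (1 fell adjusted over the list alone). Their median was 1.11, and 7 were not called. ISG15, a ubiquitin-like modifier, rose 15.3-fold from 38.1 ± 7.29 to 584 ± 161 CPM, and the exonuclease gene ISG20 rose 7.90-fold from 0.763 ± 0.349 to 6.07 ± 2.10 CPM. That list was higher by camera (adjusted p = 2.0e-04; adjusted p = 0.33 with an estimated correlation). Doxorubicin replicate 1 exceeded the mean of the other two by 0.32 on the log2 scale over the interferon list; without it, 20 members rose. Without DMSO replicate 2, or with no filter, 1 member fell. Of 19 NF-kB target genes, 12 rose, and NFKBIA, the NF-kB inhibitor, was the 1 that fell. TNFAIP3 rose 3.98-fold from 11.9 ± 2.86 to 47.5 ± 3.98 CPM and TRAF1 rose 3.94-fold. Without DMSO replicate 1, or without doxorubicin replicate 1, 2 members fell. The list was higher by camera (adjusted p = 0.0040; adjusted p = 0.33 with an estimated correlation).

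Stress-response genes mostly rose. In the list of the integrated stress response and the unfolded protein response, 18 of 24 members rose, with a median log2 fold change of 0.80. DDIT3, the transcription factor CHOP, rose 9.42-fold from 9.04 ± 0.364 to 85.2 ± 4.74 CPM, and ATF3 rose 6.61-fold from 17.6 ± 2.32 to 116 ± 1.197 CPM. Of the exon bases of DDIT3, 39.6% lie in exons of other genes. The largest overlap is with MARS1, on the opposite strand, which had 21324 counts against 5132. The 5 members that fell were HSPA5, SDF2L1, CALR, HSP90B1 and PDIA4, which encode chaperones and folding factors of the endoplasmic reticulum. The list was higher by camera (adjusted p = 0.0049; adjusted p = 0.40 with an estimated correlation). Of 27 apoptosis regulators, 14 rose and 5 fell. TNFRSF10A, a TRAIL receptor, rose 9.94-fold from 4.47 ± 0.537 to 44.5 ± 6.76 CPM, and BCL2L11, which encodes the pro-apoptotic BIM, rose 7.16-fold from 4.71 ± 1.13 to 33.7 ± 4.01 CPM. For BCL2L11 the share in exons of other genes is 10.9%, with the largest overlap in opposite-strand MIR4435-2HG, with 3824 counts against 2091. The members that fell included BCL2, BOK, BCL2L2 and CASP9, and the list was not called (adjusted p = 0.067). Of 20 immediate-early genes, 12 rose and 4 (KLF2, KLF6, ZFP36 and JUN) fell, 5 adjusted over the list alone. EGR2 rose 12.2-fold from 0.821 ± 0.313 to 10.1 ± 0.413 CPM and KLF4 rose 6.26-fold from 8.02 ± 0.951 to 50.3 ± 1.47 CPM. That list was not called (adjusted p = 0.065), but was called higher without DMSO replicate 2 (0.0389) or doxorubicin replicate 2 (0.0470). Without DMSO replicate 3, 7 members fell.

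Cholesterol synthesis genes fell: 20 of 24 fell, 11 at least 2-fold, with a median log2 fold change of -0.90. The 2 members that rose were TM7SF2, a sterol reductase gene, by 4.30-fold from 7.72 ± 2.07 to 33.2 ± 2.30 CPM, and HSD17B7. The list was lower by camera (adjusted p = 9.7e-05; adjusted p = 0.51 with an estimated correlation). Over it, doxorubicin replicate 1 was lower than the mean of the other two by 0.28 on the log2 scale; without it, 20 members fell and 2 rose. Nuclear genes of oxidative phosphorylation moved little: 5 rose (SDHA, UQCRC1, COX7B, UQCRB and COX6A1), 13 fell and 21 did not pass, with 0 members changed at least 2-fold. SDHA rose 1.56-fold from 135 ± 2.32 to 210 ± 12.9 CPM, and ATP5F1C fell 1.56-fold from 139 ± 1.45 to 88.9 ± 9.92 CPM. Camera did not call the list (adjusted p = 0.29), and without doxorubicin replicate 3 only 3 members rose. Of 25 ribosome biogenesis genes, 7 rose and 13 fell; FBL, the methyltransferase fibrillarin, fell 2.08-fold from 110.2 ± 6.51 to 52.9 ± 2.70 CPM and RRP12 rose 2.04-fold from 93.8 ± 7.32 to 191 ± 24.7 CPM. That list was not called (adjusted p = 0.31).

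Among genes for the targets, transport and metabolism of doxorubicin, 6 of 19 rose and 9 fell. TOP2A (chr17:40388516-40417950), the topoisomerase of dividing cells, fell 3.53-fold from 610.3 ± 28.9 to 173 ± 19.5 CPM (adjusted p = 1.1e-11, edgeR). TOP2B (chr3:25597905-25664907), the other type II isoform, fell 1.495-fold from 118 ± 14.7 to 78.7 ± 1.95 CPM (adjusted p = 8.4e-06). XDH, xanthine dehydrogenase, rose 11.8-fold from 1.68 ± 0.865 to 20.1 ± 2.14 CPM. The list was not called (adjusted p = 0.29). Of 20 iron handling and ferroptosis genes, 8 rose and 8 fell. PTGS2, cyclooxygenase 2, rose 4.31-fold from 1.39 ± 0.403 to 6.04 ± 2.70 CPM, and HMOX1 rose as above. The list's median was 9.4e-05 and its mean 0.08, and camera did not call it (lower, adjusted p = 0.90). Leaving out DMSO replicate 1, or DMSO replicate 2, lowered the rising members to 5.

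Only 10 of 30 cardiomyocyte genes passed the expression filter. NPPB, which encodes the natriuretic peptide BNP, rose 10.5-fold from 0.619 ± 0.423 to 6.52 ± 0.881 CPM, and MEF2C, ATP2A2 and TTN also rose. TPM1, tropomyosin, fell 1.64-fold from 595 ± 68.7 to 363 ± 68.7 CPM, and DES and GJA1 also fell. Exons of other genes cover 21.4% of the exon bases of TPM1, with the largest overlap in opposite-strand TPM1-AS, with 119 counts. The median log2 fold change was -0.08, the mean was 0.20 and camera did not call the list (higher, adjusted p = 0.99). The run with no filter and DESeq2 also tested members below the expression filter. Of the 30 in the list, 10 then rose with no filter and 8 with DESeq2, against 4 in the main test. Without doxorubicin replicate 1, 5 fell. Among 29 fibroblast and extracellular matrix genes, 14 fell and 3 rose, with a median of -0.36. COL1A1, a type I collagen chain, fell 3.13-fold from 9864 ± 989.9 to 3156 ± 730.3 CPM (adjusted p = 3.0e-04), while ACTA2, smooth muscle actin, rose 7.65-fold from 8.81 ± 4.38 to 67.25 ± 1.84 CPM, and COL6A1 and POSTN also rose. Of the exon bases of ACTA2, 30.1% lie in exons of other genes on either strand. The largest overlap is with opposite-strand ACTA2-AS1, with 27 counts, and any further overlapping genes were not examined. Camera did not call the list (adjusted p = 0.062), but called it lower without DMSO replicate 3 (0.0473), doxorubicin replicate 2 (0.0364) or doxorubicin replicate 3 (0.0196). Over it, doxorubicin replicate 1 was lower than the mean of the other two by 0.45 on the log2 scale; without that library 14 members fell and 5 rose. Without the 50 most abundant genes, where fewer members were tested, 8 fell, and with library totals only 5 rose. The fall does not extend to collagen genes at large. Of 34 tested genes with the symbol prefix COL, 19 rose and 6 fell, with a median log2 fold change of 0.73. Camera over 163 such gene families did not call them (higher, adjusted p = 0.092).

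Of the markers of other cell types, part of each list was measured. Of 7 measured epithelial markers 6 rose (7 adjusted over the list alone); KRT14 rose from 1.62 ± 1.002 to 12.1 ± 2.10 CPM and KRT8 rose 2.46-fold from 38.2 ± 6.53 to 93.8 ± 4.603 CPM. Keratin genes are alike in sequence, so their counts are uncertain between copies. Exons of other genes cover 7.63% of the exon bases of KRT8, with the largest overlap in opposite-strand KRT18, with 24550 counts against 7204. The list was higher by camera (adjusted p = 0.015; adjusted p = 0.33 with an estimated correlation). Of 9 endothelial markers, FLT1, PECAM1 and ROBO4 rose, while TEK fell 1.96-fold from 14.01 ± 1.39 to 7.12 ± 0.906 CPM and ENG fell 1.63-fold from 345 ± 34.1 to 211 ± 27.3 CPM (camera adjusted p = 0.47). Of 4 measured immune markers, LAPTM5 rose 20.6-fold from 0.346 ± 0.0942 to 7.25 ± 2.15 CPM and CSF1R fell (camera adjusted p = 0.90). Without DMSO replicate 2 or doxorubicin replicate 3, 0 immune markers fell in edgeR's test, and without DMSO replicate 3, 2 rose. With DESeq2 3 immune markers rose and 0 fell, with the replicate block 2 rose, and with no filter 5 endothelial and 3 immune markers rose. DESeq2 and the run with no filter also tested genes below the expression filter.

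**Figure D3:**
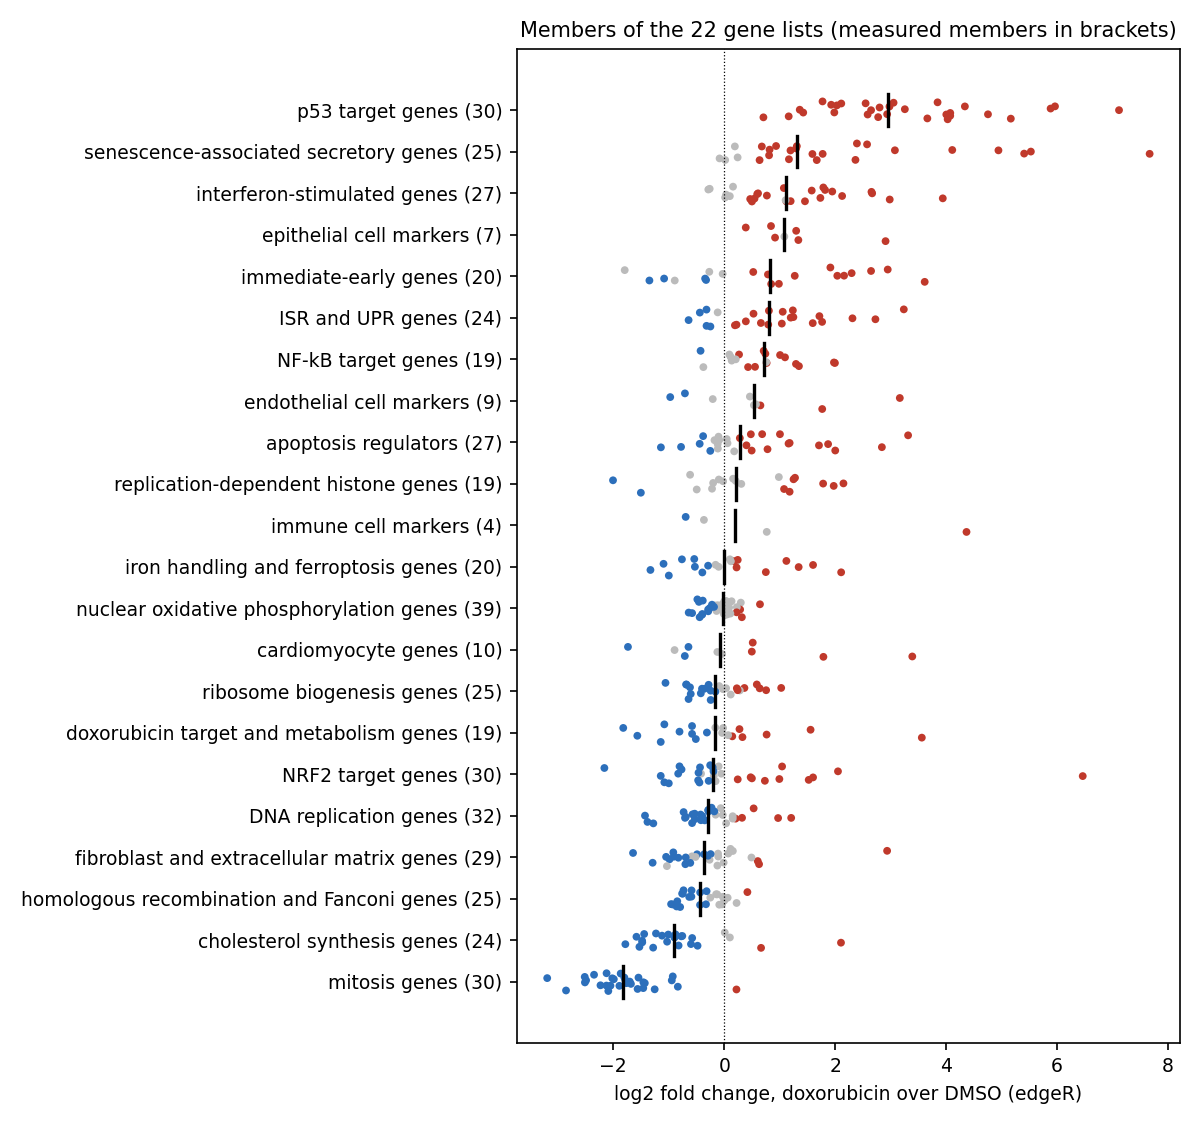
Log2 fold change (doxorubicin over DMSO, horizontal axis) of each measured member of the 22 gene lists, ordered by the list median (black bar); red members were called higher, blue lower, and grey were not called. The medians run from -1.83 for mitosis genes to 2.96 for p53 target genes; ISR and UPR are the integrated stress response and the unfolded protein response.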

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

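The test of added counts by gene type below was chosen after related values were seen; the other tests of this part were stated before their results were seen. Genes that the expression filter removed, which only the alternatives with another filter tested, held more counts after doxorubicin. These 19470 genes with at least 1 count summed to 1209 ± 41.8 CPM in DMSO and 2079 ± 121 CPM in doxorubicin (SD, n = 3), a ratio of 1.72, with every doxorubicin library above every DMSO library. The ratio was 2.45 for protein-coding genes, 1.51 for lncRNA genes and 1.41 for pseudogenes in this set. Of them, 8187 had 0 counts in DMSO and at least 1 in doxorubicin, against 1675 the other way round.

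Library depth is argued against: after thinning each library to 17000000 counts, 22354 ± 182 genes had a count in DMSO and 26815 ± 357 in doxorubicin, and the lowest doxorubicin library exceeded the highest DMSO library by 3888 genes, against ranges of 360 and 670 within the groups. Reads running in from strongly raised neighbours could not be the whole source, since genes farther than 100 kb from every gene raised at least 2-fold still had a ratio of 1.66, although genes within 5 kb of one had a higher ratio of 2.35. Carry-over of genomic DNA stays open. A first test took the 31658 genes below the filter at 0 in all DMSO libraries, with or without a count in doxorubicin. The tenth of them with most added counts held 74.3% of those counts. An even rate per base gave 53.5%, and at most 54.4% in 100 draws, so the added counts were less even than such draws. The bound stated for exclusion was 2 times the even share, which no value could reach. A second test took all protein-coding (6887) and lncRNA (11640) genes below the filter. Their added CPM per megabase of exon, protein-coding over lncRNA, was 1.597, 1.02 and 1.32 in the 3 doxorubicin libraries. Low-level transcription of otherwise silent genes after doxorubicin may also account for it, as a hypothesis that was not tested.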

How the results depend on the processing

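Scaling by library totals only was chosen after the data were seen. With 3 libraries per group the calls rest on 4 residual degrees of freedom. The counts of genes higher and lower stayed within 1.5 times 5017 and 4917 under each of the 14 settings run. They ranged from 4703 to 6100 higher and from 4494 to 5190 lower. Of the genes called in the main test, 0 were called in the opposite direction by edgeR or by DESeq2 (5035 higher, 4494 lower). All settings reuse the same counts, so a reversal was unlikely. Of the 9934 calls, DESeq2 lost 1113, the run without DMSO replicate 2 lost 933, and the other settings lost 15 to 849. The 6 libraries allow only 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split called 9934 genes and the highest other 0, where unadjusted p under 0.05 gave 43 to 128 genes. Only 1 split, the real one, reached 9934. Every other split put both treatments in each group, so a treatment effect adds to the spread within its groups. The contrast of these counts therefore gives no support of its own. At least 2-fold, 3531 genes rose with no filter, where more genes were tested, and 430 fell by glmTreat, which is stricter by construction. No pairing by replicate number was seen in the counts. Deviations of same-numbered libraries from their group means correlated at 0.05, -0.02 and 0.03, and not every library correlated best with its own number. A shared day or culture with little effect on expression cannot be excluded. With the replicate block, 5003 genes were higher and 4917 lower.

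For the gene lists the values are adjusted p, and the cause of a change was not tested. With an estimated correlation 0 lists were higher and 0 lower: the value was 0.333 for the p53, recombination, secretory, interferon, NF-kB and epithelial lists, 0.361 for mitosis, 0.634 for DNA replication, 0.404 for stress response and 0.514 for cholesterol synthesis. By fry, which does not compare a list with other genes, 12 lists were higher and 6 lower; lists then called higher were histones (0.00246), apoptosis (0.00019), cardiomyocyte (0.00438), immediate-early (0.00268), endothelial (0.0132) and immune (0.00894), those then called lower were doxorubicin handling (0.000515) and ribosome biogenesis (0.0203), and the NRF2 list turned to higher (0.454). DESeq2 statistics called apoptosis (0.0016) and immediate-early genes (0.0125) and turned the endothelial list to lower (0.922). With no filter 7 lists were lower, adding oxidative phosphorylation (0.00607), fibroblast (0.000671) and ribosome biogenesis (0.0257), and histones turned to lower (0.511). The cardiomyocyte list, never called by camera, turned to lower at 1 CPM in 3 libraries (0.998), with the replicate block (0.881), with library totals (0.996), and without DMSO replicate 1 (0.931), doxorubicin replicate 1 (0.662) or doxorubicin replicate 2 (0.816). The replicate block also called the fibroblast list (0.0374). With a library left out, the value ranged from 0.662 to 0.941 for cardiomyocyte, from 0.0196 to 0.0866 for fibroblast and from 0.0389 to 0.169 for immediate-early genes. Across genes, the rank correlation of fold change with exon length moved from -0.02 to 0.00125 at a mean log2 CPM of at least 3.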

Other observations

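The chromosome windows, the gene length test, the test of one shift for all NRF2 target genes and the single genes named here were chosen after results were seen. Beyond the fixed lists, 163 gene families sharing a symbol prefix and with at least 10 tested members were compared by camera, and 6 passed at an adjusted p under 0.05, 2 higher and 4 lower; with an estimated correlation 0 passed (adjusted p = 0.952). Nucleoporin genes (NUP) fell, 16 of 20 with 1 that rose, at a median log2 fold change of -0.45 (adjusted p = 0.0082); NUP88 fell from 120.2 ± 1.76 to 68.5 ± 4.42 CPM. Splicing factor genes of the SRSF family fell, 8 of 11 with 0 that rose in edgeR's test, at a median of -0.56 (adjusted p = 0.032); SRSF2 fell from 192 ± 3.14 to 67.3 ± 6.35 CPM. Of 14 proteasome regulatory subunit genes (PSMD), 11 fell and 0 rose (1 rose with library totals only), at a median of -0.40 (adjusted p = 0.040), and of 31 kinesin genes (KIF), some also in the mitosis list, 21 fell and 6 rose (adjusted p = 0.032). Of 10 lipid transporter genes (ABCA), 7 rose and 0 fell, at a median of 1.46 (adjusted p = 0.032); ABCA1 rose from 2.58 ± 2.04 to 101.8 ± 12.7 CPM. The median of each family kept its direction under the 4 other scalings. That decides nothing, since those scalings moved the median of all tested genes by at most 0.04.

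Protein-coding zinc finger genes with the prefix ZNF rose more often than they fell, 194 against 54 of 443, at a median of 0.27 (camera adjusted p = 0.032). Of 703 windows of 2 Mb, chr19:52000001-54000000 (GRCh38) held more genes at least 2-fold higher than its share, 20 of 42 (Fisher's test, adjusted p = 1.6e-04). Of these, 18 were among the window's 34 ZNF genes, counted here over any gene type. Outside the window, 169 of 413 protein-coding ZNF genes rose and 54 fell. The window chr12:48000001-50000000 held 10 of 37 genes at least 2-fold lower (Fisher's test, adjusted p = 0.046), among them the alpha-tubulin genes TUBA1A, TUBA1B and TUBA1C, which are near-identical copies. Fisher's test treats genes as independent, which neighbouring members of a family need not be, so the p-values of these windows may be too small. The non-coding RNA H19 (chr11:1995176-2001470) had 2 counts over the DMSO libraries and 2878 over the doxorubicin libraries, a ratio of 1460 with a 95% counting interval of 404 to 12059.

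The mixed direction of the NRF2 target genes was weighed against 2 technical explanations. Over all tested genes, 5017 were higher and 4917 lower, so a mixed direction need not be particular to this list. A scaling factor shifts every gene alike, so scaling is argued against as the source of the spread between members. Of the 30 members, 10 lay more than 3 SE above the list median and 11 more than 3 SE below it. These counts stay the same under any one shift, so they cannot show where 0 lies. How many members rose and how many fell still depends on the scaling. The median log2 fold change of the members called lower, -0.47, decides nothing by itself, since the 4 other scalings moved the median of all tested genes by at most 0.04 and left it at -0.43 or below. Reads shared between near-identical copies are argued against as the whole source: without the 8 members that have such copies, 11 members fell and 8 rose of the 22 left. A real difference in how single NRF2 target genes respond to doxorubicin, several of which other regulators also control, may account for it, as a hypothesis that was not tested. A hypothesis that long genes fell more, as can be argued for a topoisomerase poison, was tested as well: Spearman's rho across tested genes between log2 fold change and exon length was -0.025, and 0.162 in the fifth of genes with the lowest expression. With genomic span, nearer to the transcribed length, it was -0.042, and the median log2 fold change was -0.08 in the tenth of genes with the longest span and 0.03 in the tenth with the shortest. Genes are not independent replicates.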
